A study of Mus musculus with 5 samples.

How the data were processed

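The deposited values are UMI counts per gene and cell barcode for 27998 Ensembl genes in each of 5 libraries, made by the authors with Cell Ranger against mm10. Per the file headers the version was 3.0.2 for PK 4NQO and 5.0.1 for the other libraries. Per the labels the libraries used 3' v2 chemistry, after removal of lymph nodes and digestion with collagenase, hyaluronidase, DNase I and Dispase II. BPK 4NQO replicate 2 shared at most 2 barcodes with any other library, against 26 to 107 among the other pairs. Its library preparation may therefore differ from that label. The authors had already called cells, and each deposited barcode holds at least 500 UMIs. The cell-calling rule, the annotation release and the Cell Ranger options are not given in the sources used here. The 4NQO dose stated in the labels was not used here, because its unit is in doubt.

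Total UMIs per library ran from 27383717 to 64169843, and median UMIs per barcode from 2523 to 15195.5. Barcodes with fewer than 300 genes or more than 20% mitochondrial counts were left out, as broken or empty droplets. The mitochondrial limit removed 2.15% of barcodes of BPK vehicle, 0.84% of PK 4NQO, 1.83% and 1.74% of BPK 4NQO and 12.92% of the tumor. Doublets were scored with scrublet as carried by scanpy 1.11.5, and the top 0.8% per 1000 barcodes of each library were removed, 2117 in all. This left 31434 of 34526 barcodes.

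Counts of each cell were scaled to 10000 and log-transformed. Clustering used 2000 variable genes, 30 principal components, 20 neighbors and Leiden at resolution 1 (leidenalg 0.10.2, igraph 0.11.9), without batch integration, under Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0 and pandas 2.3.3. This gave 33 clusters, and immune cells were clustered again into 21. Clusters were named from markers of 21 classes. A cluster took the class with the highest mean z-score of its markers over clusters. That score had to exceed 0.5, at least 3 markers had to be found in at least 25% of its cells, and no other class could hold more markers among its top 10 genes by fold. Shallow clusters without such a marker, and clusters that failed a condition, stayed unnamed. Markers, comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The thresholds of the naming rule, which was revised once, and the second clustering of immune cells were chosen afterwards.

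Shares are percents of kept cells, or of epithelial cells for the epithelial classes, with exact Clopper-Pearson 95% intervals. Ratios compare the mean log2 share of BPK 4NQO with the single library of the other group. Shares carry no test. The share of keratinocyte-like cells of all cells was added after it was seen.

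For gene tests raw counts were summed per library and class where each compared library held at least 30 cells, giving 18 tests. They were run with edgeR 4.0.16 (limma 3.58.1, R 4.3.3): filterByExpr by group, TMM factors, the quasi-likelihood F test and Benjamini-Hochberg adjustment within each test, with calls at an adjusted p under 0.05. The treatment and genotype contrasts came from 1 model of the gland libraries and share the BPK 4NQO libraries, so genes found in both are not independent findings. The tumor contrast used a model that also held the tumor. Each model had 1 residual degree of freedom among samples, which comes from the BPK 4NQO pair, so the single libraries are assumed to vary like it. The variance of each gene was moderated across genes. Standard errors are the absolute log2 fold change over the square root of F. A group at 0 counts is given as a bound against a floor of 3 counts per library, and a group with 1 to 3 counts as a ratio with an exact counting interval. Where the single library is the low one, both use the mean CPM of the BPK 4NQO libraries, so 1 of these can lie outside them. The interval covers the counting error of the low group alone, not the spread between the BPK 4NQO libraries. The keratinocyte test of the tumor comparison was added after the class was seen to be large.

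Beside the calls over all genes, 28 gene lists were summarised by members past the threshold, members past it when adjusted over the list alone, the median log2 fold change and its percentile among 10000 random lists matched on mean expression within 100 ranks. The percentile leaves out correlation between list members, and no set test was run. Which lists are described with examples was decided after the results were seen. Named genes are the largest changes on each side with at least 32 CPM on average and the same side in both BPK 4NQO libraries, leaving out Xist and Y-linked genes, immunoglobulin and T cell receptor segments, hemoglobin, predicted models, mitochondrial and ribosomal protein genes and markers of another class. Among genes chosen by these rules, 2 are not reported here. Locations are from the GENCODE mouse annotation M21.

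Alternatives were DESeq2 1.42.0, RLE factors, no filter on low counts, only the libraries of the compared groups in the model, doublets kept, a mitochondrial limit of 10%, Leiden resolution 2, and leaving out either BPK 4NQO library. Chosen after the data were seen were the models without luminal alveolar cluster 2 and hormone-sensing cluster 4 and the counts of calls kept without a replicate. These clusters had the highest median UMIs of their class among clusters without Top2a as a top gene and with under 50% of their cells from 1 library. The deeper hormone-sensing cluster 26, mostly of tumor cells, was kept. The edgeR test was tested on simulated data with 200 changed genes in each of 4 settings. For the luminal alveolar treatment test 24% of 4-fold and 80% of 16-fold changes were recovered, with 2 false calls among 98, and for the basal genotype test 14% and 86%, with 8 among 103. All simulated libraries varied around a common mean by the fitted dispersion, so these rates hold only where single libraries vary like the BPK 4NQO pair. The false calls in data with different mixes of clusters were not tested. The sizes of 16-fold and 64-fold were added after the first run. Figures were drawn with matplotlib 3.10.9, and adjusted p-values outside R came from statsmodels 0.14.6. No trajectory, copy number or sequence variant analysis was done, and raw reads were not used here.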

Results

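Single-cell transcriptomes were measured by 3' droplet sequencing of mouse mammary gland and of 1 mammary tumor, in 5 libraries. The mice carried Krt14cre, floxed Trp53 and either 1 floxed Brca1 allele (BPK) or wild-type Brca1 (PK). Glands received 12 intraductal injections of the carcinogen 4NQO, a quinoline that forms bulky DNA adducts, or of the PBS and PEG vehicle. The BPK tumor had formed after 24 injections of 4NQO. The groups were BPK vehicle (1 library), PK 4NQO (1), BPK 4NQO (2) and BPK tumor (1). Total depth was 64169843 UMIs over 9610 barcodes in BPK vehicle, 35281954 over 7512 in PK 4NQO, 46938491 over 7632 in BPK 4NQO replicate 1, 27383717 over 7118 in replicate 2 and 58754764 over 2654 in the tumor. After filters 31434 of 34526 barcodes were kept, from 8649 cells in BPK vehicle to 2234 in the tumor. Median UMIs per barcode ran from 2523 in BPK 4NQO replicate 2 to 15195.5 in the tumor. Only BPK 4NQO was replicated, and the labels do not say whether its libraries come from separate animals. The p-values rest on the spread between these libraries, moderated across genes. A gene can therefore pass although its replicates lie far apart, and a small p-value does not show that they are alike. Replicate 2 shared at most 2 barcodes with any other library, so the spread may include a difference in library preparation.

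Brca1 (ENSMUSG00000017146, mm10 chromosome 11, 101488764 to 101551955) was near the detection limit in every library. It reached 1.66 CPM (counts per 1e6 UMIs) over all cells in BPK vehicle (Poisson 95% interval 1.34 to 2.03), 1.07 (0.74 to 1.49) in PK 4NQO, 1.05 (0.76 to 1.40) and 4.69 (3.88 to 5.62) in BPK 4NQO replicates 1 and 2, and 2.23 (1.86 to 2.65) in the tumor. Trp53 (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873) was at 48.6, 44.3, 45.1, 27.2 and 14.2 CPM in the same order. Among tumor cells Trp53 was at 5.20 CPM (4.55 to 5.92) in keratinocyte-like cells and at 36.6 (30.9 to 43.0) in hormone-sensing luminal cells. In the keratinocyte-like cells of BPK 4NQO it was at 24.1 (15.9 to 35.1) and 12.4 (6.79 to 20.8). The sources used here do not give the deleted exons, and a 3' tag outside the deleted part does not check a genotype.

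Clusters were named from marker genes as luminal alveolar (milk-producing lineage), luminal hormone-sensing, basal (myoepithelial) and keratinocyte-like epithelium, fibroblasts, endothelium, pericytes and immune classes. Keratinocyte-like cells came from clusters 11 and 15, each with 4 markers of the class in at least 25% of its cells. Among epidermal genes, Krtdap was a top gene of cluster 11, and Krt79 and Lgals7 were top genes of cluster 15. Cluster 15 held 98.9% and 96.3% of these cells in BPK 4NQO replicates 1 and 2. Cluster 11 held 77.1% of those of the tumor. Few of these cells held a UMI of Krt1, Lor or Flg, at 1.13% and 3.67% in BPK 4NQO and 6.55% in the tumor. Cells of unnamed clusters made up 4.50% of BPK vehicle, 3.11% of PK 4NQO, 5.64% and 9.96% of BPK 4NQO replicates 1 and 2, and 2.28% of the tumor. Shares below carry no test, because 2 libraries against 1 cannot reach p under 0.05 in an exact test.

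**Figure D1:**
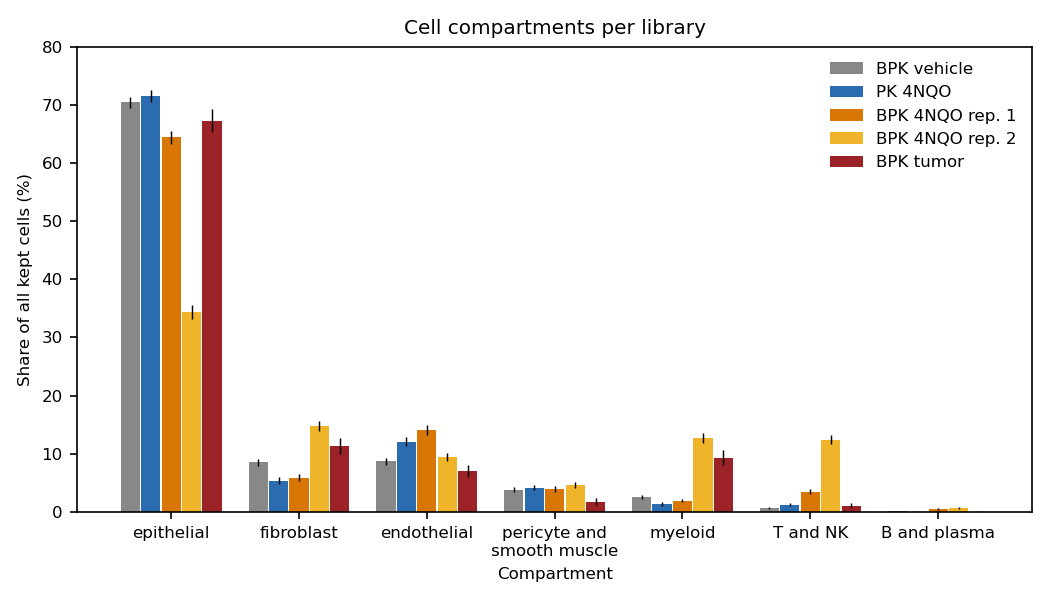
Share of kept cells (percent) held by each compartment in each of the 5 libraries, with Clopper-Pearson 95% intervals. Myeloid cells held 12.6% and T and NK cells 12.4% of BPK 4NQO replicate 2, against 1.90% and 3.41% of replicate 1.

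The treatment comparison set BPK 4NQO (n = 2) against BPK vehicle (n = 1) and asks what the carcinogen does to the Brca1 heterozygous gland. T cells and keratinocyte-like cells held larger shares of both 4NQO libraries. In luminal alveolar cells 5 of 20 interferon-stimulated and 3 of 7 MHC class II genes rose, and in hormone-sensing cells 2 of 20 proliferation genes fell, neither called by DESeq2. Fibroblasts carried more Saa3, Serpinb2 and Ereg, which encode secreted inflammatory, protease-inhibiting and growth factor proteins.

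T cells were 0.127% of BPK vehicle cells (11 of 8649, 95% interval 0.064 to 0.227) and 2.33% and 10.7% of BPK 4NQO replicates 1 and 2, with a mean of 6.53% ± 5.94 (SD, n = 2). The log2 ratio was 5.30, and 4.20 without replicate 2 or 6.40 without replicate 1. NK cells and innate lymphoid cells were 0.486% against 1.08% and 1.69%. Plasma cells numbered 22 and 28 in the BPK 4NQO libraries and 0 in BPK vehicle (95% interval up to 0.043%). The immune compartment was 3.56% of BPK vehicle and 6.73% and 28.1% of BPK 4NQO, a log2 ratio of 1.95 that was 0.92 without replicate 2 and 2.98 without replicate 1. Macrophages were 2.30% of BPK vehicle, below it in replicate 1 at 1.68% and above it in replicate 2 at 10.5%.

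Keratinocyte-like cells were 0.127% of all BPK vehicle cells (11 cells) and 2.53% and 3.33% of BPK 4NQO, with a mean of 2.93% ± 0.566 (SD, n = 2). The log2 ratio of 4.51 fell to 2.34 when doublets were kept, and at the finer clustering BPK vehicle held none of them. Of epithelial cells, luminal alveolar cells were 41.4% in BPK vehicle and 33.1% and 24.0% in BPK 4NQO, and hormone-sensing cells 31.1% against 41.0% and 35.7%. Basal cells were 27.3% against 22.0% and 30.6%, a difference smaller than the spread between replicates. Cluster 16, with Upk3a, Fgb and Cited1 among its top genes, held 27.1% of hormone-sensing cells of BPK vehicle, 2.05% and 2.36% of those of BPK 4NQO and 6.27% of those of PK 4NQO. Of luminal alveolar cells, cluster 8 held 10.3% in BPK vehicle, 16.2% in PK 4NQO and 34.0% and 36.5% in BPK 4NQO, and cluster 2 held 30%, 38.4%, 37.2% and 11.9%. Gene tests of these classes compare different mixes of clusters. The plot of class shares shows each library.

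**Figure D2:**
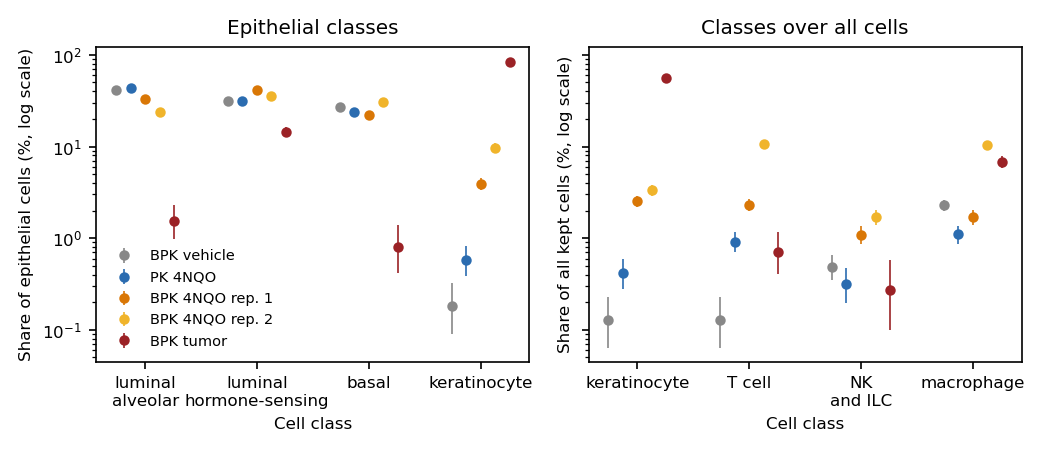
Share of cell classes (percent, log axis) of epithelial cells (left) and of all kept cells (right) in the 5 libraries, as points with Clopper-Pearson 95% intervals. Keratinocyte-like cells lay at 0.127% of BPK vehicle cells, at 2.53% and 3.33% of BPK 4NQO and at 56.0% of the tumor.

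Gene expression was compared on counts summed per class and library with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05, with 1 residual degree of freedom among samples. In luminal alveolar cells 37 of 13541 genes rose and 9 fell. Ubd, which encodes a ubiquitin-like modifier induced by interferon gamma (ENSMUSG00000035186, chromosome 17, 37193892 to 37196095), rose with a log2 fold change of 7.40 (SE 0.99, adjusted p 2.94e-08), from 0.499 CPM to 111 and 59.6. Clca1, which encodes a chloride channel regulator, rose by 5.96 (SE 0.95, adjusted p 6.82e-06). It belongs to a family with close paralogs, lay at 3.85 and 105 CPM in the replicates, gave 2.16 without replicate 2 and 6.94 without replicate 1, and was not called by DESeq2. Of the 46 calls, 46 moved the same way by at least 1 log2 unit without replicate 1 and 40 without replicate 2, where 4 had no value. With only the compared libraries in the model 5 genes passed and Clca1 did not.

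Hormone-sensing cells had 21 genes higher and 15 lower of 12848, and 2 genes in all by DESeq2. Ctsr, a placental-type cathepsin gene with close paralogs (ENSMUSG00000055679, chromosome 13, 61159204 to 61164256), rose by 5.31 (SE 1.20, adjusted p 0.00851), from 3.96 CPM to 90.7 and 224, and by 4.52 without replicate 2. In basal cells 21 genes rose and 3 fell of 11188, against 3 by DESeq2. Iigp1, which encodes an interferon-induced GTPase (ENSMUSG00000054072, chromosome 18, 60376027 to 60392634), rose by 4.96 (SE 0.95, adjusted p 0.000376), from 4.01 CPM to 139 and 112, and by 5.90 with doublets kept. Lars2, the mitochondrial leucyl-tRNA synthetase gene, passed at 5.95 (SE 1.20, adjusted p 0.0011) through replicate 2 alone: it was at 8.86 CPM in vehicle, 9.07 in replicate 1 and 1090 in replicate 2, gave 0.03 without replicate 2 and 6.94 without replicate 1, and was not called by DESeq2. Lars2 was also a top gene of unnamed cluster 18, beside Gm26917, Gm42418 and mitochondrially encoded genes. That cluster had a median of 912 UMIs and 71.6% of its cells from replicate 2. Whether these reads come from Lars2 transcripts was not tested. Cluster 17 held 91.2% of the basal cells of replicate 2 and 1.00% of those of replicate 1, where cluster 0 held 96.8%. Without replicate 2, 25 of the 36 hormone-sensing and 12 of the 24 basal calls moved the same way by at least 1 log2 unit, and 9 and 7 had no value.

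Fibroblasts had 26 genes higher and 5 lower of 10421, and 13 higher by DESeq2. Serpinb2, which encodes a plasminogen activator inhibitor (ENSMUSG00000062345, chromosome 1, 107511423 to 107535478), was at 2 counts in vehicle and at 298 and 220 CPM in BPK 4NQO. That is a ratio of 245 with a 95% counting interval of 67.8 to 2020 (adjusted p 0.000608). Saa3, which encodes an acute-phase amyloid (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700), rose by 8.35 (SE 1.89, adjusted p 0.008), with 5.92 CPM in vehicle, 3806 in replicate 1 and 89.5 in replicate 2. Its change was 3.90 without replicate 1 and 9.30 without replicate 2, and DESeq2 did not call it. Car3, a carbonic anhydrase gene of fat and muscle, fell by 2.95 (SE 0.71, adjusted p 0.0181), to 0.757 and 19.4 CPM from 87.6. It fell by 6.68 without replicate 2 and by 2.18 without replicate 1, and lost its call with DESeq2, with no count filter and with doublets kept. Cluster 25 held 28.2% of the fibroblasts of replicate 2 and at most 0.24% of those of the other libraries. Cluster 21, with Saa3, Timp1 and Cxcl5 among its top genes, held 0.95% of the fibroblasts of BPK vehicle, 5.60% of those of PK 4NQO and 10.5% and 10.2% of those of BPK 4NQO, so the groups compared differ in their mix of clusters. All 31 calls kept their direction by at least 1 log2 unit without either replicate.

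Endothelial cells had 21 genes higher and 2 lower of 10265, and 7 higher by DESeq2. The mix of clusters differed: cluster 9 held 19.0% of the endothelium of BPK vehicle, 40.3% of PK 4NQO and 25.4% and 58.8% of BPK 4NQO, and cluster 6 held 65.6%, 46.1%, 63.2% and 29.7%. Ccl21a, which encodes a lymphoid chemokine and has near-identical copies, was at 1 count in vehicle and at 933 and 468 CPM in BPK 4NQO, a ratio of 1150 (207 to 45500, adjusted p 7.4e-05). Its log2 fold change of 9.98 was 5.62 with doublets kept and 9.38 without replicate 1. Ubd was at 3 counts against 80.6 and 231 CPM, a ratio of 88.6 (30.3 to 429, adjusted p 0.00322), with 6.32 on the log2 scale and 5.38 without replicate 2. In macrophages 0 of 6662 genes passed edgeR's quasi-likelihood test, with 96 at an unadjusted p under 0.05 and 0 by DESeq2. Clusters immune 0 and immune 10 held 69.2% and 20.4% of the macrophages of replicate 2 and at most 0.85% of those of any other library. T cells and keratinocyte-like cells were too few in BPK vehicle to test.

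Members of the interferon-stimulated list rose in 4 of the 6 classes tested. In luminal alveolar cells 5 of 20 rose and 15 did not pass, 16 rose adjusted over the list alone, and the median log2 fold change was 2.41. Ifit3 rose by 4.46 (SE 1.01, adjusted p 0.00807), Cxcl10 by 3.05 (SE 0.75, adjusted p 0.0253), and Rsad2 by 3.39 (SE 0.72, adjusted p 0.00305), or by 1.88 without replicate 2 and 4.15 without replicate 1. In basal cells 3 of 17 rose, with 11 adjusted over the list alone and a median of 1.98: Ifit1 by 4.94 (SE 0.93; 5.85 with doublets kept, 4.15 without replicate 1), Rtp4 by 3.41 (SE 0.80; 4.23 and 2.37) and Oasl2 by 3.04 (SE 0.78; 3.94 with doublets kept). In fibroblasts Ifi44 rose, 1 of 19, with 11 adjusted over the list alone and a median of 2.16. Ifi44 was at 0 counts in vehicle, and its mean over the replicates was at least 18.7-fold above a floor of 3 counts in that library. In endothelium Zbp1 rose, 1 of 18, from 2 counts by a ratio of 26.8 (7.41 to 221), with 1 adjusted over the list alone and a median of 1.24. Hormone-sensing cells had 0 of 19 past edgeR's threshold, 5 adjusted over the list alone and a median of 1.45. Macrophages had 0 of 20 by both counts and a median of 1.75, or 0.86 and 2.24 for the replicates taken singly on log2 of CPM + 0.5. Each of these 6 medians lay at percentile 100.0 of 10000 random lists matched on expression. The random genes were drawn independently, so any correlation between list members is left out, and the 6 classes come from the same libraries. The percentiles are therefore not a test. DESeq2 did not call the 3 basal genes or Zbp1, and with only the compared libraries in the model the luminal alveolar examples and Oasl2 lost their calls.

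MHC class II genes, which encode antigen presentation to helper T cells, passed in 3 of the 6 classes tested. In luminal alveolar cells 3 of 7 rose, 4 did not pass and 4 rose adjusted over the list alone, with a median of 2.76, or 2.40 and 0.77 for single replicates. Cd74 rose by 4.30 (SE 0.92, adjusted p 0.00309), from 9.90 CPM to 238 and 153, H2-Ab1 by 3.64 (SE 0.78, adjusted p 0.00309) and H2-Aa by 3.25 (SE 0.74, adjusted p 0.00807), or 2.62 without replicate 1. Without cluster 2, a deep luminal alveolar cluster, these were 4.95, 4.31 and 3.96, and with only the compared libraries in the model the calls ended. In fibroblasts 2 of 6 rose, with 5 adjusted over the list alone and a median of 3.34, or 3.93 and 1.99 for single replicates: Cd74 by 4.57 (SE 1.14, or 3.58 without replicate 1) and H2-Aa by 4.06 (SE 1.02, or 3.32 without replicate 1), which DESeq2 did not call. In basal cells H2-Ab1 rose, 1 of 5, by 3.51 (SE 0.84; 4.92 with doublets kept, 2.86 without replicate 1), with 3 adjusted over the list alone, and lost its call with no count filter. In endothelium 0 of 6 passed over all genes and 5 rose adjusted over the list alone, with a median of 3.01. In hormone-sensing cells 0 of 7 passed and 3 rose adjusted over the list alone, with a median of 0.85, or 0.22 and 0.78 for single replicates. In macrophages 0 of 8 passed by either adjustment, with a median of -0.37. C1qa, a macrophage gene, marks how much macrophage RNA other droplets hold. In replicate 1 it was at 1.57 CPM in luminal alveolar cells and 4337 in macrophages, and Cd74 at 232 and 14267. In replicate 2, C1qa was at 16.9 and 2053, and Cd74 at 177 and 12278. Basal cells of replicate 2 held C1qa at 33.7 and Cd74 at 168, so relative to macrophages Cd74 did not exceed C1qa there. Hormone-sensing cells of replicate 2 held C1qa at 16 and Cd74 at 87.8, where Cd74 did not exceed C1qa in the same sense. Fibroblasts of replicate 2 held C1qa at 12.7 and Cd74 at 106. In replicate 1 basal cells held them at 3.40 and 260 and fibroblasts at 3.56 and 261.

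**Figure D3:**
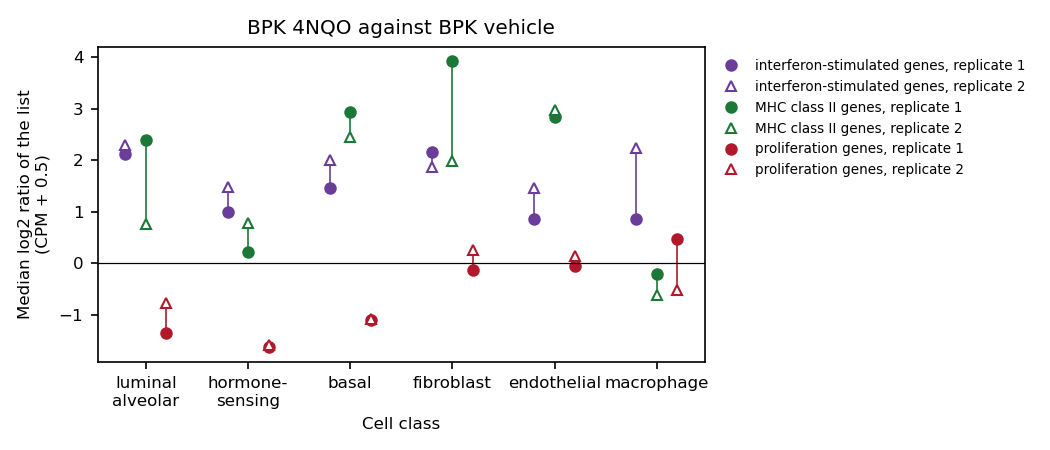
Median log2 ratio (CPM + 0.5) of 3 gene lists in BPK 4NQO against BPK vehicle, for 6 cell classes, with 1 point per BPK 4NQO replicate. Interferon-stimulated genes lay above 0 in both replicates of every class shown.

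Few proliferation genes passed. In hormone-sensing cells Ccnb2 fell by 2.78 (SE 0.64, adjusted p 0.00991) and Birc5 by 2.61 (SE 0.64, adjusted p 0.0232), 18 of 20 did not pass, 10 fell adjusted over the list alone, and 20 of 20 lay lower in both replicates. Both calls ended with DESeq2, with doublets kept and without cluster 4, a deep hormone-sensing cluster, while the changes stayed at -2.61 and -2.57 with doublets kept and at -2.49 and -2.44 without that cluster. Of 20 genes in luminal alveolar cells 0 passed edgeR's threshold and 3 fell adjusted over the list alone, with a median of -0.98, and basal cells had 0 and 3 with a median of -1.06. Cluster 10, with Ube2c, Cenpf and Top2a among its top genes, held 28.1% of luminal alveolar cells of BPK vehicle, 4.15% and 7.04% of those of BPK 4NQO and 8.03% of those of PK 4NQO.

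Among inflammatory genes of fibroblasts 2 of 17 rose, Saa3 and Cxcl5, and 2 adjusted over the list alone. Cxcl5 rose by 4.01 (SE 1.04, adjusted p 0.0388), or 2.59 without replicate 1 and 4.71 without replicate 2, and lost its call with no count filter and with only the compared libraries. Of 18 senescence-associated secreted genes 2 rose, Ereg and Cdkn2a, with 3 adjusted over the list alone. Ereg was at 3 counts in vehicle and 123 and 21.6 CPM in BPK 4NQO, a ratio of 43.2 (14.8 to 209, adjusted p 0.00251), with 5.28 on the log2 scale, 3.56 without replicate 1 and 6.04 without replicate 2. Cdkn2a, which encodes p16 and p19, rose by 4.55 (SE 1.15, adjusted p 0.031), or 3.71 without replicate 1. Inflammatory genes past the threshold elsewhere were Cxcl5 in luminal alveolar cells and Ccl8 in hormone-sensing, basal and endothelial cells. Cxcl5 rose by 4.91 (SE 0.96; 3.60 without replicate 2, 5.67 without replicate 1, 5.75 without cluster 2), but not with only the compared libraries, and DESeq2 called Ccl8 in none of the 3 classes. Ccl8 was at 3.73 in hormone-sensing and 4.20 in basal cells, or 2.23 and 2.08 without replicate 2 and 4.50 and 5.07 without replicate 1. In endothelium, with 0 counts in vehicle, it had no value without replicate 2. In replicate 2 Ccl8 stood at 17.1, 40.4 and 44.0 CPM in the 3 classes and 1748 in macrophages, and C1qa at 16, 33.7 and 48.6 and 2053. Relative to macrophages the 2 genes were of similar size, so macrophage RNA stays open as the source of Ccl8 in replicate 2. In simulated data for the fibroblast test 2% of genes changed 2-fold were recovered, 10% at 4-fold, 58% at 16-fold and 90% at 64-fold, so most changes of the smaller sizes were not detectable.

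The genotype comparison set BPK 4NQO (n = 2) against PK 4NQO (n = 1). It asks how glands with 1 floxed Brca1 allele and Krt14cre differ from those with wild-type Brca1 under the same exposure. Whether the allele was deleted in any class, stromal and immune classes included, was not checked. The BPK 4NQO libraries again held more T cells and keratinocyte-like cells. Among chemokine and MHC class II genes Cxcl5, Ccl8 and H2-Aa rose in luminal alveolar cells, and DESeq2 did not call Cxcl5 or Ccl8. In replicate 2 Ccl8 stood, relative to macrophages, close to the macrophage gene C1qa, so macrophage RNA stays open as its source there. PK 4NQO was processed with Cell Ranger 3.0.2 and the other libraries with 5.0.1, per the file headers, so the software version differs together with the genotype.

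T cells were 0.916% of PK 4NQO cells (64 of 6987, 95% interval 0.706 to 1.168), against 2.33% and 10.7% of BPK 4NQO, a log2 ratio of 2.45 that was 1.34 without replicate 2 and 3.55 without replicate 1. Keratinocyte-like cells were 0.415% of PK 4NQO (29 cells), against 2.53% and 3.33%, a log2 ratio of 2.80 that fell to 1.68 with doublets kept and to 1.06 at the finer clustering. Plasma cells were 0 of 6987 (95% interval up to 0.053%). The immune compartment was 3.18% of PK 4NQO, a log2 ratio of 2.11 that was 1.08 without replicate 2 and 3.14 without replicate 1. Luminal alveolar cells were 43.8% of epithelial cells, against 33.1% and 24.0%.

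In luminal alveolar cells 16 of 13541 genes rose and 0 fell in edgeR's quasi-likelihood test, with 287 at an unadjusted p under 0.05 and 6 rising by DESeq2. Clca1 passed at 4.75 (SE 0.89, adjusted p 0.00046), with 0.96 without replicate 2, 5.74 without replicate 1, 5.73 with doublets kept and 6.56 without cluster 2, and Lars2 at 4.61 (SE 1.07, adjusted p 0.0272), with 0.03 and 5.60. DESeq2 called neither, and neither passed with only the compared libraries. In hormone-sensing cells 20 genes rose and 2 fell of 12848. Ctsr rose by 6.39 (SE 1.29, adjusted p 0.00156), from 1.86 CPM to 90.7 and 224, or 5.61 without replicate 2. In basal cells 17 rose and 2 fell of 11188, and DESeq2 called 0. Hist1h2ap, 1 of many similar histone genes, passed at 4.73 (SE 0.94, adjusted p 0.00122), with 2.44 without replicate 2 and 5.60 without replicate 1, and basal Lars2 at 6.28 (SE 1.24), with 0.37 and 7.28. Without replicate 2, 8 of 16 luminal alveolar, 12 of 22 hormone-sensing and 9 of 19 basal calls kept their direction by at least 1 log2 unit, and 4, 6 and 6 had no value.

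Outside the epithelium few genes passed the threshold. In fibroblasts 1 rose and 1 fell of 10421 in edgeR's quasi-likelihood test, with 260 at an unadjusted p under 0.05. Lars2 was at 1 count (1.33 CPM) in PK 4NQO, with 9.85 CPM in replicate 1 and 750 in replicate 2. Its ratio for the mean of the replicates was 329 (59.0 to 13000, adjusted p 0.0121), an interval that leaves out the spread between them. Its log2 fold change of 8.10 was 2.79 without replicate 2 and 9.07 without replicate 1, and it lost its call with DESeq2 and with doublets kept (5.20). Endothelial cells had 8 higher and 0 lower of 10265 by edgeR, with 98 at an unadjusted p under 0.05 and 1 by DESeq2. Ccl21a was at 3.74 CPM in PK 4NQO against 933 and 468, a change of 7.52 (SE 1.49, adjusted p 0.00152) that fell to 3.10 and lost its call with doublets kept and was 6.94 without replicate 1. Ctss, a lysosomal protease gene of antigen-presenting cells, was at 0 counts in PK 4NQO, 5.06 CPM in replicate 1 and 117 in replicate 2 (adjusted p 0.000144). The mean of the replicates was at least 35.8-fold above a floor of 3 counts in the PK library, or 1.81 CPM, mostly through replicate 2. DESeq2 did not call Ctss. In replicate 2 endothelium held Ctss at 124.5 CPM against 6435 in macrophages, and the macrophage gene C1qa at 48.6 against 2053, before TMM scaling.

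Lepr, the leptin receptor gene (ENSMUSG00000057722, chromosome 4, 101717404 to 101815352), was the 1 gene past the threshold in macrophages. It fell from 27 counts in 77 PK 4NQO macrophages to 3 counts in all in BPK 4NQO, a ratio of 204 (69.6 to 987, adjusted p 0.000208), with -7.70 on the log2 scale, -6.14 without replicate 2, -8.34 without replicate 1 and -6.89 with doublets kept. In T cells 0 of 5343 genes passed edgeR's quasi-likelihood test, with 66 at an unadjusted p under 0.05 and 0 by DESeq2. Clusters immune 2 and immune 9 held 53.5% and 19.8% of the T cells of replicate 2 and at most 3.12% of those of any other library, where immune 1 held the rest. Keratinocyte-like cells were too few in PK 4NQO to test.

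Few inflammatory cytokine and chemokine genes passed in the 3 epithelial classes. In luminal alveolar cells 2 of 19 rose, Cxcl5 and Ccl8, with 4 adjusted over the list alone, 17 not past the threshold and a median of 1.48, or 0.28 and 1.22 for single replicates. Cxcl5 was at 1 count in PK 4NQO and at 3.54 and 14.8 CPM in BPK 4NQO, a ratio of 178 (32 to 7050, adjusted p 0.000106), with 6.98 on the log2 scale, 5.70 without replicate 2, 7.74 without replicate 1 and 9.88 with doublets kept. Ccl8 was at 1 count in PK 4NQO in luminal alveolar cells, a ratio of 162 (29.0 to 6380). It also rose in hormone-sensing cells, 1 of 19 with 5 adjusted over the list alone, and in basal cells, 1 of 15 with 1 adjusted over the list alone. In the 3 classes Ccl8 was at 6.80, 5.97 and 4.06 on the log2 scale, and at 5.00, 4.49 and 1.95 without replicate 2. DESeq2 called none of these. Ccl8 stood at 16.6 CPM in luminal alveolar cells and 1748 in macrophages of replicate 2, and C1qa at 16.9 and 2053. Relative to macrophages the 2 genes were of similar size, so macrophage RNA stays open as the source of Ccl8 in that library. Of 7 MHC class II genes in luminal alveolar cells H2-Aa rose by 3.07 (SE 0.73, adjusted p 0.0386), or 2.45 without replicate 1, and 4 rose adjusted over the list alone, with a median of 2.55, or 2.30 and 0.66 for single replicates. The H2-Aa call ended with only the compared libraries and without cluster 2, where the change was 3.14. Interferon-stimulated genes had 0 past edgeR's threshold in each class, with 2 adjusted over the list alone in luminal alveolar, hormone-sensing and basal cells and medians of 0.90, 0.90 and 0.78. Of 16 senescence-associated secreted genes in hormone-sensing cells Plau rose from 0 counts, to a mean of the replicates at least 15.2-fold above a floor of 3 counts in the PK library. Of 14 in basal cells Ereg rose from 2 counts, a ratio of 24.8 (6.87 to 205), with 4.30 on the log2 scale and 3.01 without replicate 2. Both calls ended with DESeq2 and with doublets kept.

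The tumor comparison set the BPK tumor (n = 1) against the BPK 4NQO glands (n = 2) and asks how the tumor differs from the exposed gland. Keratinocyte-like cells made up most of the tumor and alveolar cells were few, while the low share of basal cells reversed at the finer clustering. In tumor keratinocyte-like cells 12 of 20 interferon-stimulated and 5 of 6 MHC class II genes fell. In tumor endothelium 4 of 16 activation and tip cell genes and 5 of 19 proliferation genes rose, and in tumor fibroblasts 3 of 22 matrix and activated fibroblast genes. The tumor received 24 injections and the glands 12, so the dose differs together with the tissue.

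Keratinocyte-like cells were 56.0% of tumor cells (1252 of 2234, 95% interval 54.0 to 58.1) and 2.53% and 3.33% of BPK 4NQO, a log2 ratio of 4.27 that was 6.0 with doublets kept and 7.25 at the finer clustering. Of epithelial cells in the tumor they were 83.2%, hormone-sensing cells 14.4%, luminal alveolar cells 1.53% (23 cells) and basal cells 0.798% (12 cells). Their log2 ratios to BPK 4NQO were -1.41 for hormone-sensing, -4.20 for luminal alveolar and -5.03 for basal cells. The basal ratio turned to 1.25 at the finer clustering. Neutrophils were 2.33% of the tumor (52 cells) and 1 and 2 cells of the BPK 4NQO libraries. T cells were 0.716% (16 cells), a log2 ratio of -2.80 that was -1.70 without replicate 2 and -3.91 without replicate 1. Macrophages were 6.85%, between the replicates' 1.68% and 10.5%. Different clusters held these classes in the tumor and in the glands. Cluster 11 held 77.1% of tumor keratinocyte-like cells and at most 3.67% of those of BPK 4NQO. Cluster 26 held 96.3% of hormone-sensing cells of the tumor and at most 0.87% of those of BPK 4NQO. Cluster 21 held 91.3% of tumor fibroblasts, against 10.5% and 10.2%. Cluster 9 held 91.7% of tumor endothelium, against 25.4% and 58.8%, and cluster immune 8 held 93.5% of tumor macrophages and 0 of those of BPK 4NQO.

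In keratinocyte-like cells 155 of 9362 genes rose and 235 fell, in a test chosen after this class was seen to be large. Prl8a9, a prolactin family gene with close paralogs, and Lce3c, a cornified envelope gene from a cluster of similar genes, were at 0 counts in both BPK 4NQO libraries. They were at least 36.0-fold and 30.5-fold higher in the tumor, at 118 and 99.5 CPM, against a floor of 3 counts per library, each with an adjusted p of 6.18e-10. Iigp1 fell by 6.63 on the log2 scale (SE 1.49, adjusted p 0.000889), from 407 and 424 CPM to 4.18, and by 5.00 with doublets kept. Clca3a2, a chloride channel regulator gene with close paralogs, fell by 6.25 (SE 1.42, adjusted p 0.00104), from 230 and 368 CPM to 3.93, and by 5.30 with doublets kept. Of the 390 calls 374 kept their direction by at least 1 log2 unit without replicate 2 and 387 without replicate 1, and 10 and 1 had no value. With doublets kept 90 genes passed.

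Interferon-stimulated genes fell in tumor keratinocyte-like cells: 12 of 20 fell, 8 did not pass, 17 fell adjusted over the list alone and the median was -3.61. Cxcl10 fell by 5.70 (SE 1.41, adjusted p 0.00355), from 388 and 387 CPM to 7.47, or 4.18 with doublets kept, Ifit1 by 5.48 (SE 1.11, adjusted p 0.000137), or 4.61 without replicate 1 and 4.65 with doublets kept, and Ifit3 by 5.21 (SE 1.53, adjusted p 0.0226), or 4.52 without replicate 1. Of 6 MHC class II genes 5 fell, 6 adjusted over the list alone, with a median of -3.88, or -4.42 and -1.88 for single replicates. Cd74 fell by 4.50 (SE 1.39, adjusted p 0.0348), from 1862 and 277 CPM to 47.4. It fell by 2.38 without replicate 1 and by 5.24 without replicate 2, and was not called with doublets kept (1.92) or with no count filter. Among MHC class I genes Nlrc5, a transcription factor gene of that pathway, fell, 1 of 12, with 3 adjusted over the list alone, and lost its call with doublets kept. Of 12 myoepithelial contractile genes 4 fell and 6 adjusted over the list alone, with a median of -2.07, or -2.61 and -1.11 for single replicates. Oxtr, the oxytocin receptor gene, fell by 5.84 (SE 1.06, adjusted p 1.56e-05). Of 18 senescence-associated secreted genes 7 rose and 2 fell, with 8 and 2 adjusted over the list alone. Mmp13, a collagenase gene, rose by 5.45 (SE 1.03, adjusted p 3.26e-05), or 6.68 without replicate 2, and Mmp10 by 5.16 (SE 0.99, adjusted p 4.78e-05), or 4.53 without replicate 1 and 7.43 without replicate 2. Hgf fell by 6.27 (SE 1.05, adjusted p 1.2e-06), or 4.73 without replicate 2. Il1a rose by 4.25 (SE 0.86, adjusted p 0.000137), or 5.28 without replicate 1 and 3.38 with doublets kept.

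**Figure D4:**
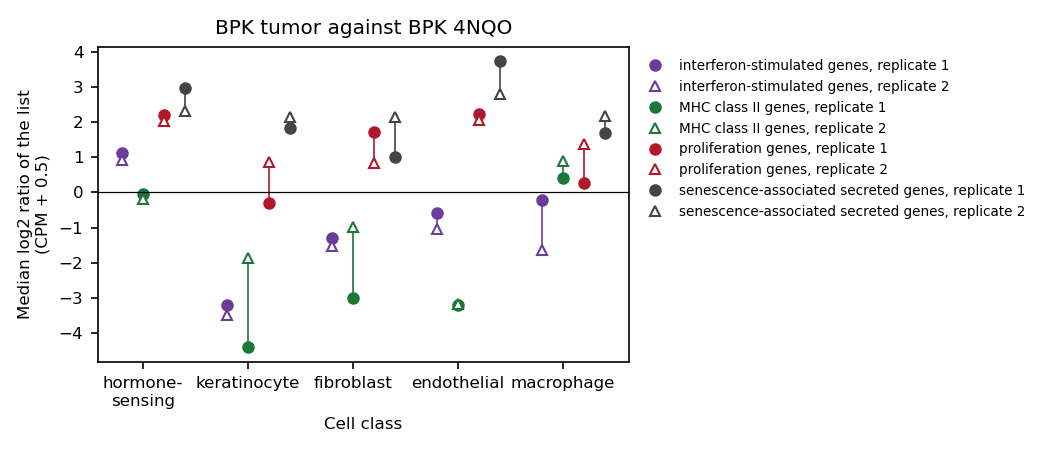
Median log2 ratio (CPM + 0.5) of gene lists in the BPK tumor against BPK 4NQO, for the classes tested, with 1 point per BPK 4NQO replicate. Interferon-stimulated genes lay below 0 against both replicates in keratinocyte-like cells and fibroblasts and above 0 in hormone-sensing cells.

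Hormone-sensing cells of the tumor had 224 genes higher and 44 lower of 12710, and 139 in all by DESeq2. Cluster 26 held 96.3% of these tumor cells. It had 11 markers of the class in at least 25% of its cells, but 0 among its top 10 genes by fold. The name of these cells is therefore less certain than that of the gland cells. Il17b, a cytokine gene that is also a top gene of basal cluster 0, rose by 5.83 (SE 0.80, adjusted p 2.99e-10), or 6.83 without replicate 1. Gdpd3, a lysophospholipase gene, fell by 4.46 (SE 1.11, adjusted p 0.00528), from 79.8 and 58.1 CPM to 3.13. Lars2 fell by 4.82 (SE 1.21, adjusted p 0.006), but by 0.76 without replicate 2, 5.77 without replicate 1 and 5.43 with doublets kept, and DESeq2 did not call it. Of 20 proliferation genes 10 rose, 15 adjusted over the list alone, with a median of 2.35. Ccnb1 rose by 4.10 (SE 0.71, adjusted p 2.87e-06), or 4.70 without replicate 1 and 3.34 with doublets kept, and Cdk1 by 3.59 (SE 0.70, adjusted p 7.14e-05), or 2.88 with doublets kept and 2.78 without cluster 4. Of 17 senescence-associated secreted genes 11 rose, with 12 higher and 1 lower adjusted over the list alone and a median of 2.79. Timp1, a metalloproteinase inhibitor gene, rose by 3.36 (SE 0.74, adjusted p 0.000855). Mmp13 and Mmp10 also rose, but DESeq2 called neither. Of 20 inflammatory genes 4 rose and 7 adjusted over the list alone, and among the 4 DESeq2 did not call Saa3 or Cxcl5. Ccl2 rose by 3.53 (SE 0.75, adjusted p 0.000445), or 4.14 without replicate 2. Krt6a in these hormone-sensing cells was at 17.8% and Krt16 at 14.5% of its level in tumor keratinocyte-like cells.

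Tumor fibroblasts had 145 genes higher and 137 lower of 10832, and 106 in all by DESeq2. Smpd3, a sphingomyelinase gene (ENSMUSG00000031906, chromosome 8, 106252548 to 106337988), was at 0 counts in the tumor and 68.8 and 640 CPM in BPK 4NQO (adjusted p 3.41e-07). The mean of the replicates was at least 582-fold above a floor of 3 counts in the tumor, or 0.699 CPM. Smpd3 was at -12.89 on the log2 scale, -10.06 without replicate 2 and -13.91 without replicate 1. It is a top gene of cluster 25, with 99.3% of its cells from replicate 2. Cxcl13, a chemokine gene for B cells, was at 0 counts in the tumor and at 190 and 16.2 CPM in BPK 4NQO, a mean at least 144-fold above the same floor (adjusted p 4.62e-08). Its log2 fold change of -11.09 was -8.61 without replicate 1 and -11.52 without replicate 2. Of 22 matrix and activated fibroblast genes 3 rose and 5 adjusted over the list alone, with a median of 0.39. Acta2, the smooth muscle actin gene, rose by 4.01 (SE 1.02, adjusted p 0.00666), from 81.4 and 98.8 CPM to 1453, and by 3.40 with doublets kept. Tagln, a contractile protein gene, rose by 3.64 (SE 0.97, adjusted p 0.0119), but was not called with doublets kept (3.08), and Ctgf by 2.78 (SE 0.82, adjusted p 0.0356). Of 18 resident fibroblast genes 1 rose and 2 fell, with 1 and 6 adjusted over the list alone and a median of -2.00. Ebf2, an adipocyte progenitor factor gene, fell by 3.49 (SE 1.05, adjusted p 0.0395), but was not called with no count filter. Of 19 interferon-stimulated genes 4 fell, 9 adjusted over the list alone, with a median of -1.72, and Cxcl10 fell by 4.13 (SE 1.10, adjusted p 0.012), or 3.44 with doublets kept. Mmp13 passed from 0 and 27.4 CPM to 914 (5.94, SE 0.99, adjusted p 8.99e-07), with 5.07 without replicate 1, 0 counts in replicate 1 and no DESeq2 call. Krt6a and Krt16 passed at 7.78 and 6.08 (SE 0.94 and 0.84), or 7.04 and 4.85 with doublets kept, but stood in tumor fibroblasts at 4.72% and 7.78% of their level in keratinocyte-like cells. In macrophages, which have other clusters, they stood at 6.82% and 8.19%.

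Endothelial cells of the tumor had 136 genes higher and 179 lower of 10584, and 142 in all by DESeq2. Of 16 activation and tip cell genes 4 rose and 4 adjusted over the list alone, with a median of 0.09: Kcne3, a potassium channel subunit gene, by 5.13 (SE 0.82, adjusted p 4.86e-07), Esm1, by 3.84 (SE 0.79, adjusted p 0.000281), or 3.12 without replicate 1 and 5.08 without replicate 2, Cxcr4 by 2.87 (SE 0.73) and Nid2 by 2.59 (SE 0.76). DESeq2 did not call Cxcr4 or Nid2. Of 19 proliferation genes 5 rose, 14 adjusted over the list alone, with a median of 2.22, and Birc5 rose by 3.40 (SE 0.73, adjusted p 0.000649). Of 6 MHC class II genes 4 fell and 5 adjusted over the list alone, with a median of -3.32. Cd74 fell by 4.44 (SE 1.22, adjusted p 0.0156), from 399 and 551 CPM to 21.7. Of 17 senescence-associated secreted genes 5 rose, with 10 higher and 1 lower adjusted over the list alone and a median of 2.97, or 3.75 and 2.81 for single replicates and 2.70 with genes at 0 counts set at their bound. Igfbp3 rose by 6.51 (SE 1.09, adjusted p 1.7e-06), from 41.2 and 21.9 CPM to 2898. Cdkn2a rose from 2 counts in all to 37.9 CPM, a ratio of 71.3 (19.7 to 589, adjusted p 3.32e-05), and stood at 230 CPM in tumor keratinocyte-like cells. With doublets kept its 6.05 on the log2 scale was 4.84. Ccl11, the eotaxin gene, was at 0 counts and at least 37.6-fold lower (adjusted p 1.56e-05). Car3 was at 0 counts and at least 109-fold below the mean of the replicates, which were at 335 and 17.8 CPM (adjusted p 7.89e-06), without a DESeq2 call. Its log2 fold change of -11.32 was -7.88 without replicate 1 and -12.31 without replicate 2. Krt6a and Dmkn, keratinocyte genes, also passed in endothelium, where Krt6a stood at 3.65% and Dmkn at 6.63% of their level in keratinocyte-like cells. Krt6a was at 0 counts in BPK 4NQO endothelium, at least 81.6-fold lower (adjusted p 6.52e-15), and Dmkn at 1 count, a ratio of 382 (68.5 to 15100).

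Macrophages of the tumor had 20 genes higher and 1 lower of 7301. Krt6a and Krt16 passed at 8.09 (SE 1.40, adjusted p 2.85e-05) and 6.21 (SE 1.22, adjusted p 0.000589), with 0 counts of either in replicate 1, and DESeq2 did not call Krt16. Csf3, which encodes a growth factor of neutrophils, rose, 1 of 16 inflammatory genes, by 5.18 (SE 1.12, adjusted p 0.00242), or 6.53 with doublets kept, with 0 counts in replicate 1, and DESeq2 did not call it. Of 15 senescence-associated secreted genes 0 passed edgeR's threshold and 7 rose adjusted over the list alone, with a median of 2.26. Luminal alveolar, basal and T cells were too few in the tumor to test. In simulated data for the tumor fibroblast test 0% of genes changed 2-fold were recovered, 16% at 4-fold, 78% at 16-fold and 90% at 64-fold.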

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

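The tests of skin, of exposure of the Brca1 heterozygous gland, of a lymph node, of library preparation, of replicate 2 alone and of immune RNA were chosen after their results were seen. The tests of doublets, of shallow barcodes and of 4NQO whatever the genotype were written beforehand. The doublet rule was once widened after its result was seen and then put back, and left doublets open both ways.

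Some lists moved in opposite directions between classes in every library compared. In the genotype comparison MHC class II genes had medians of 2.55 in luminal alveolar and 1.76 in basal cells and -1.42 in macrophages. For replicates 1 and 2 singly these were 2.30 and 0.66, 2.19 and 1.10, and -1.19 and -1.69. In the tumor comparison interferon-stimulated genes had a median of 1.06 in hormone-sensing cells and -1.72, -1.22 and -3.61 in fibroblasts, macrophages and keratinocyte-like cells. The macrophage value was -0.22 against replicate 1 and -1.65 against replicate 2. In each case the difference was not tested. Some barcodes entered no gene test. Cells of unnamed clusters, which count in the shares as kept cells and partly as immune cells, were 9.96% of BPK 4NQO replicate 2 (4.50% of BPK vehicle). Of tumor barcodes 12.92% lay over the mitochondrial limit (2.15% in BPK vehicle).

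Keratinocyte-like cells held a larger share of both BPK 4NQO libraries than of the vehicle and PK 4NQO glands. Skin carried over at dissection predicts cornified cells, and 1.13% and 3.67% of these cells held a UMI of Krt1, Lor or Flg, below the 10% set for skin but not under the 2% set against it. Doublets of 2 other classes predict no genes far above both parents, and 14 genes, among them Krt6a, Krtdap and Il24, lay at 4 times the highest other class in both libraries. The bound set beforehand was 20, and unnamed clusters were not among the parents, so doublets stay open, as does skin. The lower BPK 4NQO share was 6.08-fold the higher of the other glands. The genotype log2 ratio of 2.80 was 1.68 with doublets kept and 1.06 at Leiden resolution 2. The 6.08-fold value restates the pattern, so it cannot decide whether exposure of the Brca1 heterozygous gland raises the class. With 1 vehicle and 1 PK library that explanation stays open.

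Immune cells held a larger share of BPK 4NQO replicate 2 than of replicate 1. A lymph node left on the gland would bring B cells, and these numbered 1.71% of T cells (12 against 703), which argues against it as the source. Among cells of at least 1000 UMIs the immune share was still 5.30-fold higher (25.2% against 4.76%), so shallow barcodes kept in 1 library do not account for it. Replicate 2 shared at most 2 barcodes with any other library, against 26 to 107 among the other pairs, so another library preparation may lie behind the gap and cannot be told apart from a difference between glands, because both rest on the same library. The p-values rest on the gap between these replicates, moderated across genes, so the doubt bears on them too. No biological explanation was tested.

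Interferon-stimulated genes lay higher in BPK 4NQO than in vehicle in each of the 6 gland classes tested. Replicate 2 alone does not account for it, since the lowest class median without that library was 0.88. RNA of immune cells in other droplets was tested in the 3 epithelial classes only, so it stays open for the other classes. In these 3 it does not account for replicate 1, where the lowest ratio of the list share to the upper 95% bound for C1q genes was 102. In replicate 2 that ratio was 1.92 in basal cells, 4.36 in hormone-sensing and 12.7 in luminal alveolar cells, and the explanation stays open. A first version of this test over both libraries together gave no decision either. 4NQO may raise the list whatever the Brca1 genotype, since PK 4NQO medians over vehicle ran from 0.32 to 1.45, but single libraries of PK 4NQO and vehicle keep this open.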

How the results depend on the processing

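The models without luminal alveolar cluster 2 and hormone-sensing cluster 4 and the keratinocyte test of the tumor were chosen after the results were seen. No paired analysis was possible because the groups share fewer than 2 replicate numbers. With doublets kept 43 of 52 share values moved by less than the spread between replicates and 9 by more, and at Leiden resolution 2 44 of 50, with 5 by more and 1 changed in sign. Of 95 gene counts 63 lay within 1.5 times the count reported, 21 fell below it and 11 above. The gene values include list examples not called in the main test, which cannot lose a call, so the shares of calls lost are larger than these counts give. Among gene values DESeq2 ended 68 of 202 and added 3, RLE factors changed 0 of 206, no count filter ended 18 of 206 and only the compared groups 15 of 206. Doublets kept ended 36 of 200, added 1 and reversed 4, and leaving out clusters 2 and 4 ended 11 of 56 and reversed 1. The fits without a replicate have no test, and direction changed for 5 of 206 without replicate 1 and 2 of 202 without replicate 2. Causes were not tested unless stated.

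With doublets kept the log2 ratio of the keratinocyte-like share of all cells was 2.34, 1.68 and 6.0 for treatment, genotype and tumor, and of epithelial cells 2.91, 2.28 and 5.49. That of B and plasma cells for genotype was 3.17, and in the tumor that of hormone-sensing cells was -0.995 and of basal cells -3.75. At Leiden resolution 2 the keratinocyte-like ratio of all cells was 1.06 for genotype and 7.25 for the tumor, and of epithelial cells 1.56 and 6.79. The treatment ratio could not be computed there, since the vehicle held none. In the tumor the luminal alveolar ratio was -3.82 and the basal ratio reversed to 1.25. For these the cause was not tested. At a mitochondrial limit of 10% 52 of 52 shares moved by less than the spread. Leaving out a replicate cannot exceed that spread, so the report gives each replicate.

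With DESeq2 the treatment counts were 2 in hormone-sensing, 3 in basal, 13 in fibroblast and 7 in endothelial cells. The genotype counts were 6 in luminal alveolar, 2 in hormone-sensing, 0 in basal, 0 in fibroblast and 1 in endothelial cells. The tumor counts were 139 in hormone-sensing, 106 in fibroblast and 142 in endothelial cells. With doublets kept the treatment counts were 75 in luminal alveolar, 14 in hormone-sensing, 57 in basal and 13 in endothelial cells. The genotype counts were 40 in luminal alveolar cells, 9 in hormone-sensing cells and 3 in macrophages, and the tumor counts 36 in macrophages and 90 in keratinocyte-like cells. Without clusters 2 and 4 treatment gave 76 and 18 genes in luminal alveolar and hormone-sensing cells, and genotype 25 and 12. With only the groups compared in the model luminal alveolar counts were 5 for treatment and 5 for genotype, and tumor macrophages had 32. RLE factors gave 34 in luminal alveolar and 1 in T cells for genotype, and no filter on low counts 27 in luminal alveolar cells and 1 in fibroblasts. In these too the cause was not tested.

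Direction changed for some genes. Over the fits without a replicate, treatment Top2a ran from -1.71 to 0.17 in luminal alveolar and from -0.83 to 0.30 in basal cells, and basal Mki67 from -1.47 to 0.63 (0.00 with doublets kept). In hormone-sensing cells Bst2 ran from -0.22 to 1.01 and Ifi35 from -0.34 to 0.43. For genotype basal Top2a ran from -0.57 to 0.56 and fibroblast Plau from -0.11 to 2.84. Csn2 in hormone-sensing cells turned to -0.50 with doublets kept and -0.17 without cluster 4 for treatment. For the tumor it turned to 1.91 and Csn1s2a to 0.59 with doublets kept. The cause was not tested. A change of 4-fold was recovered for 10% of simulated genes in the treatment fibroblast test and 24% in the luminal alveolar test. Whether more depth or more libraries would raise this was not tested.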

Other observations

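Which lists are given here with their members, and the comparisons of levels between classes, were chosen after the results were seen.

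Cdkn2a, which encodes p16 and p19, was at 5.97 CPM in fibroblasts of BPK vehicle, 138 in PK 4NQO, 208 and 98.7 in BPK 4NQO and 508 in the tumor, before TMM scaling. Mmp13 in the tumor was at 834 CPM in fibroblasts, 334 in macrophages, 294 in keratinocyte-like cells and 68.6 in hormone-sensing cells. Cd74 in endothelium was at 17.0 CPM in BPK vehicle, 478 in PK 4NQO, 388 and 612 in BPK 4NQO and 20.6 in the tumor. Skeletal muscle cells numbered 45 in BPK vehicle, 16 in PK 4NQO, 0 and 3 in BPK 4NQO and 0 in the tumor. Mast cells numbered 14 in BPK 4NQO replicate 2.

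Hypoxia and glycolysis genes rose in 7 of 301 tests of a gene in a class, each in the tumor comparison and from 4 genes, among them Ankrd37 at 4.76 and Eno1 at 3.52 in endothelium (5.50 and 4.17 without replicate 1) and Pgk1 at 3.09 in keratinocyte-like cells (2.38 with doublets kept). Replication stress and DNA repair genes rose in 3 and fell in 0 of 267 such tests, with Rrm2 at 3.34 in tumor hormone-sensing cells (4.15 without replicate 1, 2.64 without cluster 4). The p53 targets rose in 5 and fell in 3 of 327. Mesenchymal genes rose in 4 and fell in 1 of 152, with Fn1 at 3.79 in tumor hormone-sensing cells (2.97 without replicate 1, 5.73 without replicate 2, 2.89 with doublets kept). Milk genes rose in 1 and fell in 4 of 200, oxidative stress genes 0 and 1 in 308, and hemoglobin genes, whose copies are nearly identical, 1 and 5 in 31.

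Other lists held no gene past the threshold of edgeR's quasi-likelihood test in any class. These were mitochondrially encoded genes (180 tests, class medians from -0.31 to 0.27), epithelial junction and keratin genes (115, -0.69 to 0.35), hormone-sensing genes (32, -1.04 to 0.13), and dissociation and immediate early genes (324, -1.22 to 0.44). In macrophages they were alternatively activated (42, -0.80 to 1.68), tumor-associated (60, -0.29 to 0.28) and inflammatory monocyte genes (39, -0.21 to 0.96). In T cells of the genotype comparison they were effector (14 tests, median -0.76), exhaustion (12, 0.31), regulatory (8, 0.08) and naive genes (9, 0.84, or 0.52 with genes at 0 counts at their bound). Adjusted over each list alone, 2 dissociation genes fell, 1 junction gene rose, and 3 monocyte genes rose and 1 fell.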
